A study of Drosophila melanogaster with 6 samples.

How the data were processed

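ATAC-seq peak lists of 6 samples of sorted midgut progenitors were analysed, 3 controls and 3 H1 RNAi samples, grouped by their titles in the labels. Per the submitters' processing notes, Trim Galore, Bowtie2, Picard and MACS2 were used with the dm6 build of the Drosophila genome; their order, versions and settings, and any shift of reads for the Tn5 cut, are not given in the sources used here. The deposited files are 1 narrowPeak list per sample, so peaks were called per sample and replicates were not pooled. Each deposited list gives a peak's start, end and summit position (other units, coordinates), an integer score, a fold enrichment over the local background (a ratio), and the −log10 of a p-value and of a q-value, all as the authors' peak caller wrote them. The lowest −log10 q of the lists lay between 2.00 and 2.05. The fold, score, p and q of a peak are the authors' own values and were used to rank and filter peaks within a list. Heights of single peaks were not compared between samples. Alternative settings with a minimum fold or −log10 q put the same cut on all 6 lists, so they also depend on height. A fold of at least 4 kept 3007 of 10872 peaks in control B and 6143 of 9827 in H1 RNAi B. No list held columns of other samples.

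A background level, which reflects depth in part, was read from the lists themselves, a step chosen after seeing the data. MACS2 writes the fold as coverage plus a pseudocount of 1 over background plus 1, and the p-value as a Poisson tail above the coverage, so each peak can be solved for its fragment coverage at the summit and its background. Between 99.95% and 100% of peaks per list came out within 0.02 fragments of a whole number, against 3.73 to 5.78% with the tail including the coverage. The most frequent background in each list, which is also the lowest, was taken as the genome-wide background in fragments per base. It scales with the number of fragments and with the length to which the caller extends them. Read totals were not used here. While the files were being examined, a comparison of summit coverage between samples was tried under 3 scalings. It pointed to differences between the groups at regions called in all 6 samples. It was left out of the results and of the scripts, because heights of single peaks were not to be compared between samples. No value of it is given, no conclusion is drawn from it, and genotype, background and shortest peak width differ between the samples as well. Apart from the settings with a minimum fold or q, the statements on the groups rest on where peaks were called. None of them speaks against a difference in height.

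Annotation came from the NCBI gene table of the dm6 assembly, which gives a start and end for each gene and no strand, transcripts or sequence. The planned promoter was therefore replaced by 500 bp on either side of both ends of a protein-coding gene, and the planned 2 kb upstream by 2 kb on either side. A gene locus is the gene and those flanks. Exons and introns could not be told apart and were merged as gene body. The planned motif search and the share of peaks in soft-masked repeats need the genome sequence and were not run. All genes of the 21 lists were matched to the table, 8 of them through newer symbols.

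Overlapping peaks (1 bp or more) were merged into regions. Gained regions were called in 3 of 3 H1 RNAi samples and 0 of 3 controls, lost regions the reverse, and the sum was compared with that of the 9 other splits of the samples into 3 and 3. Values per sample were compared by exact two-sided permutation of the group labels, whose smallest p is 0.1, and gene lists and region classes by two-sided Fisher exact tests, with Benjamini-Hochberg adjustment and a threshold of 0.05. Regions of one locus are not independent, and p-values over regions do not measure the spread between samples. The replicates are separate collections of guts per the labels. Named regions were, in each direction, up to 12 in the locus of a protein-coding gene with a symbol other than a CG number, ranked by the lowest percentile of their peaks by −log10 q within each list, plus up to 6 genes per list and a fixed set (esg, Delta, pros, sc, nub and the His1 genes).

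The tests, the gene lists, the naming rule and most alternatives were fixed before the data were examined. The alternatives were a −log10 q of at least 10, a fold of at least 4, lists cut to the 6142 highest-ranked peaks, reciprocal overlap of 50%, summits clustered within 150 bp, 2 of 3 in place of 3 of 3, the major arms alone, wider gene windows, other backgrounds, the replicate letter as a block, and leaving out each sample. Added after seeing the data were lists without the TE sequence, further settings for the position and list tests, the stricter q, the fold minimum and equal lengths for each named region and the fixed genes, and the tests of the closing section other than the sample splits. The region code was tested on simulated lists of 9723 regions, where 200 of 200 planted gained and 200 of 200 planted lost regions were called, and the coverage step on 3000 simulated summits, of which 100% were solved exactly. The simulated lists held no other partly called regions, left out short and closely spaced regions, and gave both groups peaks of like width. They checked the code and not how merging treats wide and narrow peaks. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.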

Results

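Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase cuts and tags open DNA, in progenitor cells of the Drosophila melanogaster midgut. The progenitors are intestinal stem cells and enteroblasts, the committed daughters of the stem cells. They were marked with GFP under the temperature-sensitive escargot driver, which is active in these cells, and sorted by flow cytometry from female flies. The 6 samples formed 2 groups of 3: controls carrying the driver and GFP, and flies that also carried an RNAi transgene against the linker histone H1, which binds the nucleosome and the DNA between nucleosomes. RNAi was induced for 4 days at 29 °C, and each replicate (A, B and C) held 50000 to 100000 cells from 70 guts. The comparison asks which parts of the genome open or close in progenitors when H1 is depleted.

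The control lists held 6142, 10872 and 8602 peaks and the H1 RNAi lists 6564, 9827 and 7261 (replicates A, B and C in each case). Genome-wide background, which rises with depth and with the length of the extended fragments, differed between the libraries. At the peak caller's level it was 5.04, 20.7 and 10.1 fragments per base in controls A, B and C. It was 5.26, 4.83 and 8.28 in the H1 RNAi samples A, B and C. Control B, the library with the highest background, also had the longest list and the largest covered length, 6.92 Mb, against 2.75 Mb in control A. H1 RNAi B reached 9827 peaks at the lowest background of the 6 libraries.

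The H1 genes themselves could not be followed in these lists. None of the 23 annotated His1 copies had a peak within 500 bp of either gene end in any of the 6 samples, and the same held for all 111 replication-dependent histone genes, which lie in a repeated array on chromosome 2L. RNAi acts on the transcript, so accessibility at the array would not show the depletion, and the knock-down was not checked here.

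Genes that define the midgut lineage had open gene ends in both groups. The progenitor factor esg (chromosome 2L, 15333866 to 15336138), the enteroendocrine proneural gene sc (chromosome X, 396060 to 397497) and the enterocyte factor nub (chromosome 2L, 12587625 to 12628135) each had a peak at a gene end in all 3 controls and all 3 H1 RNAi samples. Delta, the Notch ligand of the stem cells (chromosome 3R, 19302731 to 19326217), had one in 3 controls and in 1 H1 RNAi sample. The enteroendocrine factor pros (chromosome 3R, 11328480 to 11407627) had one in 2 controls and in 1 H1 RNAi sample. This difference was 0 with a −log10 q of at least 10, with a fold of at least 4 and with lists of equal length. Both loci, counted as the gene and 2 kb on either side, held at least 1 peak in all 6 samples. At Delta the difference, H1 RNAi samples minus controls, stayed at −2 with lists of equal length and with a window of 1000 bp. It was −1 with a −log10 q of at least 10. Only with peaks of a fold enrichment of at least 4 did the balance at Delta turn, with 1 more H1 RNAi sample than controls.

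The number and extent of called peaks overlapped between control and H1 RNAi samples. Controls had 8539 ± 2366 peaks (SD, n = 3) and H1 RNAi samples 7884 ± 1718 (SD, n = 3; exact two-sided permutation p = 0.8). Covered length was 5.21 ± 2.18 Mb in controls and 3.43 ± 0.440 Mb in H1 RNAi samples (SD, n = 3 each; exact permutation p = 0.4). Median peak width was 485 ± 108 bp and 358 ± 50.9 bp (SD, n = 3 each; exact permutation p = 0.2). With 3 samples against 3 the smallest p that this test can give is 0.1, and the difference in peak number turned to 512 more peaks in the H1 RNAi samples without control B, to 5.33 more without H1 RNAi A, and to 882 more with peaks of a fold of at least 4. Without control A the groups no longer overlapped in covered length (a difference of −3.005 Mb) or median width (−187 bp), each at the smallest exact permutation p of 0.1.

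**Figure D1:**
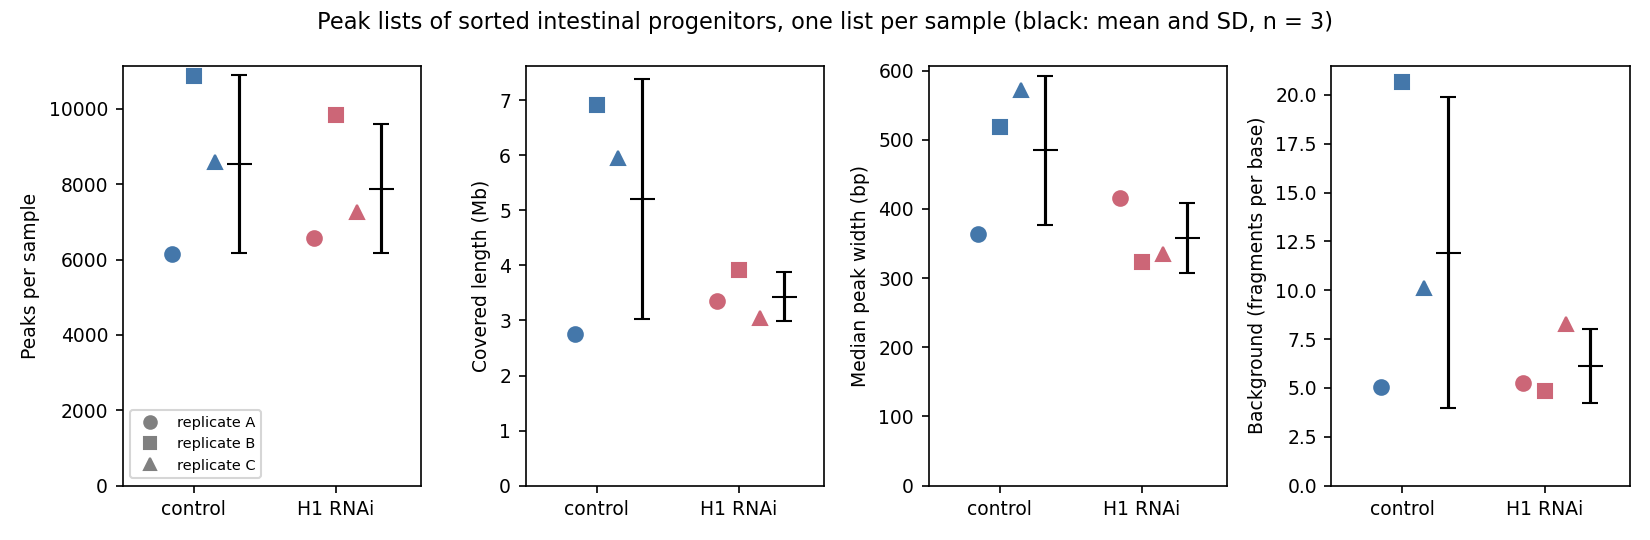
Peaks per sample, covered length (Mb), median peak width (bp) and genome-wide background (fragments per base) for each control and H1 RNAi sample, with the marker showing the replicate letter and the black bar the mean and SD of 3 samples. The groups overlap in each panel, and control B has the most peaks (10872), the longest covered length (6.92 Mb) and the highest background (20.7).

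H1 is known to act in 2 compartments, heterochromatin and transposon sequence. Peaks on chromosome 4, Y and unplaced scaffolds and on transposon sequence did not differ between the groups beyond the spread between samples. Pericentric heterochromatin of the other chromosomes was not part of this measure. Spans next to the centromeres are taken up in the closing section. Peaks on chromosome 4, Y and unplaced scaffolds made up 1.26 ± 0.146% of the control lists and 1.6 ± 0.514% of the H1 RNAi lists (SD, n = 3 each; exact permutation p = 0.4), and H1 RNAi C had the highest share, 2.19%. Without H1 RNAi C the difference shrank from 0.335 to 0.0383 percentage points. The parts went opposite ways: chromosome 4 had 79.3 ± 34.1 peaks in controls and 72.3 ± 16.6 in H1 RNAi samples (SD, n = 3 each; exact permutation p = 0.9), and Y and unplaced scaffolds 30 ± 13 and 51.7 ± 32.7 (SD, n = 3 each; exact permutation p = 0.5). Females normally carry no Y, so peaks placed on it do not report Y heterochromatin in these cells. On the sequence named TE, which by its name collects transposable elements, controls had 156 ± 22.1 peaks and H1 RNAi samples 157 ± 22.0 (SD, n = 3 each; exact permutation p = 1). These peaks covered 154 ± 56.5 kb in controls and 138 ± 38.4 kb in H1 RNAi samples (SD, n = 3 each; exact permutation p = 0.7). Which element a TE position belongs to was not given in the sources used here. The X chromosome held 17.7 ± 0.964% of the control peaks and 18.3 ± 0.443% of the H1 RNAi peaks (SD, n = 3 each; exact permutation p = 0.5).

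The share of peaks within 500 bp of an end of a protein-coding gene was 49.1 ± 2.11% in controls and 48.2 ± 4.04% in H1 RNAi samples (SD, n = 3 each; exact permutation p = 0.8). The difference of −0.976 percentage points was larger with a −log10 q of at least 10 (−4.86, p = 0.4), with a fold of at least 4 (−5.23, p = 0.4) and with lists of equal length (−3.18, p = 0.5), by the same exact permutation test. Its sign turned with a window of 1000 bp, to 0.355 percentage points higher in H1 RNAi, and without H1 RNAi C, to 1.29 points higher.

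Of 21 gene lists fixed before the data were examined, 0 had control and H1 RNAi values that did not overlap (10% would by chance). The Benjamini-Hochberg adjusted exact permutation p was 1 for all 21. The replication-dependent histone list stood at 0% in each sample, so its test had nothing to compare. The share of genes with a peak at a gene end, given as mean ± SD over 3 samples, was 42.7 ± 12.5% in controls and 37.2 ± 8.03% in H1 RNAi samples over all 13946 protein-coding genes. Intestinal progenitor genes (13 genes, among them the transcription factor Sox21a and the Notch receptor gene N) stood at 92.3 ± 7.69% in controls and 84.6 ± 15.4% in H1 RNAi samples. The 11 Notch target genes of the E(spl) complex stood at 42.4 ± 5.25% and 39.4 ± 5.25%, and the 10 JAK/STAT pathway genes at 70.0 ± 17.3% and 73.3 ± 5.77%. The 72 Polycomb-target developmental regulators, such as wg and Dll, stood at 55.1 ± 8.02% and 57.9 ± 6.85%.

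Markers of differentiated gut cells did not differ beyond the spread between samples either. Enteroendocrine genes, including hormone genes such as Tk and NPF, had a peak at a gene end in 25.6 ± 9.68% of 26 members in controls and in 20.5 ± 5.88% in H1 RNAi samples. For the 45 enterocyte genes, mostly digestive enzymes, the shares were 30.4 ± 10% and 28.1 ± 3.39%. The 19 visceral muscle genes stood at 28.1 ± 11% and 26.3 ± 5.26%, and the 21 synaptic and neuronal genes at 19.0 ± 4.76% and 17.5 ± 7.27%. Hemocyte genes (12 genes) stood at 33.3 ± 8.33% in controls and 25.0% in each H1 RNAi sample, fat body genes (12) at 36.1 ± 17.3% and 30.6 ± 9.62%, and tracheal genes (10) at 30.0% in each control and 30.0 ± 10% in H1 RNAi samples. Female germline and follicle genes (25) stood at 17.3 ± 10.1% and 13.3 ± 2.31%, and male germline genes (23) at 24.6 ± 10% and 18.8 ± 9.05%.

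Among lists of cell state and growth, immune genes varied little between replicates and the others widely. Cell cycle genes (29) stood at 69.0 ± 30.1% in controls and 54.0 ± 26.3% in H1 RNAi samples. DNA damage, apoptosis and JNK genes (25) stood at 70.7 ± 20.1% and 62.7 ± 15.1%, heat shock genes (18) at 68.5 ± 21.0% and 64.8 ± 17.9%, and antimicrobial and immune genes (29) at 23.0 ± 3.98% and 21.8 ± 1.99%. Genes in pericentric heterochromatin (20) stood at 50.0 ± 22.9% and 41.7 ± 16.1%, and heterochromatin and piRNA silencing genes (23) at 56.5 ± 19.0% and 40.6 ± 22.3%. Cytoplasmic ribosomal protein genes (87) stood at 75.1 ± 18.7% in controls and 63.2 ± 14.4% in H1 RNAi samples.

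**Figure D2:**
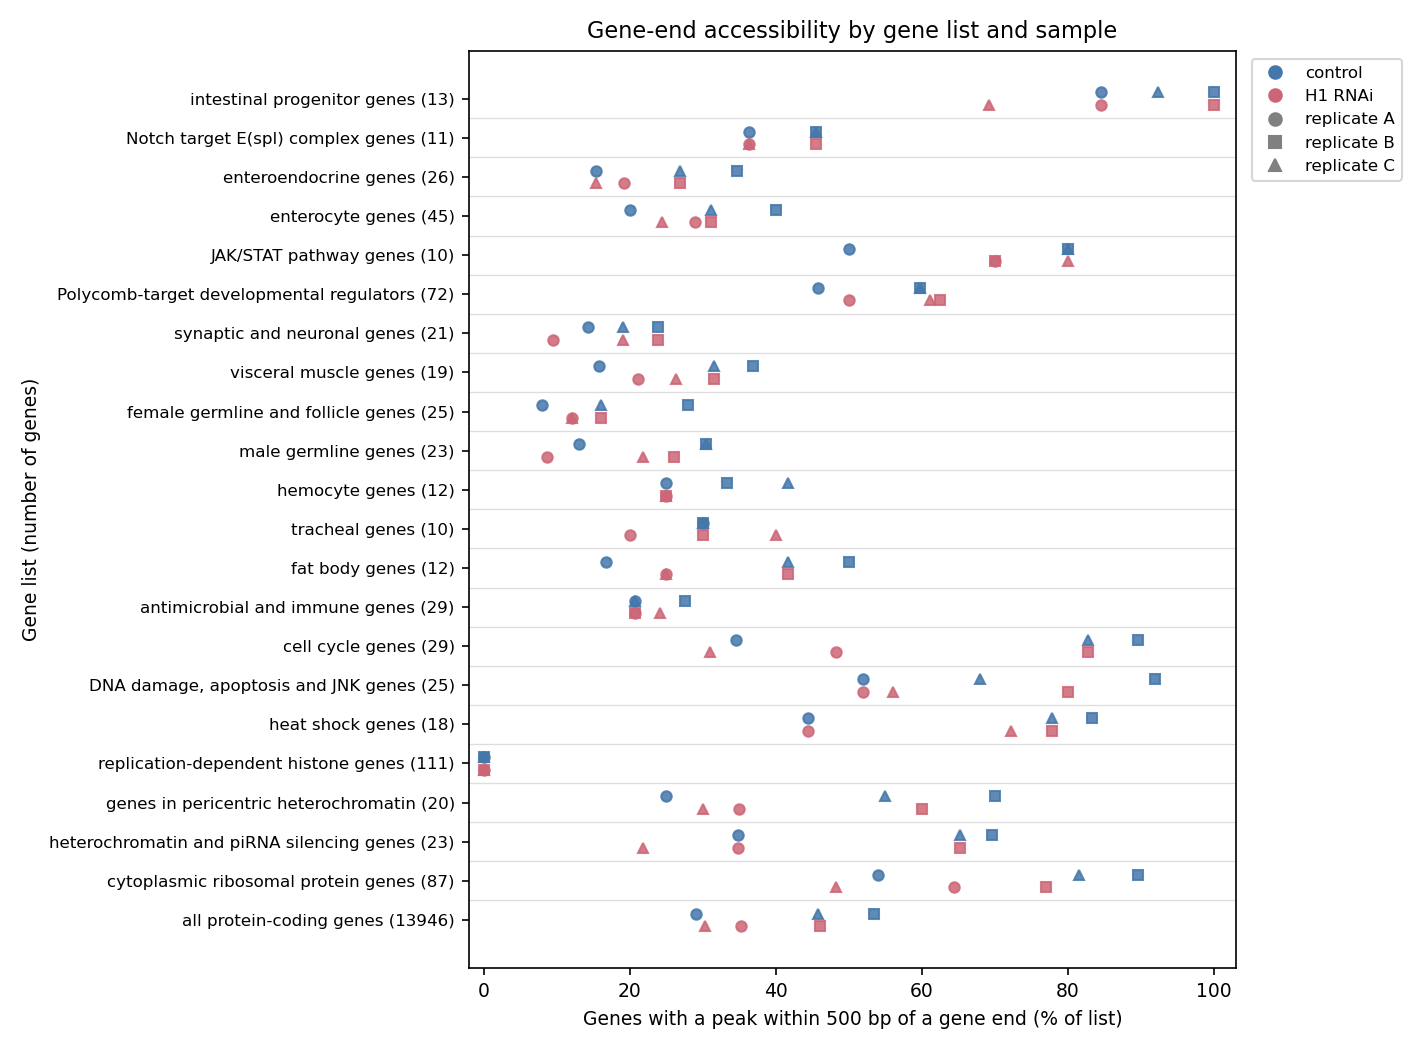
Share of the genes in each list (x axis, percent; number of genes in brackets) with a peak within 500 bp of a gene end, 1 point per sample, coloured by group and shaped by replicate. Control and H1 RNAi points overlap in all 21 lists, and the progenitor list reaches 69.2% or more in each sample.

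Region by region, a small set of sites was called in one group alone, but splits that mix the groups gave such sites too. Merging overlapping peaks of the 6 lists gave 11854 regions, of which 4366 were called in all 6 samples. A further 22 regions were called in all 3 H1 RNAi samples and in no control (gained), and 73 in all 3 controls and in no H1 RNAi sample (lost). Of the 9 other splits of the samples into 3 and 3, 2 gave more such regions (116 and 570) than the 95 of the real one. Of these, 16 gained and 60 lost regions lay in the locus of a protein-coding gene, meaning the gene or 2 kb on either side. The median width was 316 bp for gained and 527 bp for lost regions, a difference that was not tested. By construction, gained regions hold only H1 RNAi peaks that touch no control peak, and lost regions only control peaks. This does not hold for reciprocal overlap and clustered summits, where a gained site can lie inside a control peak. No single region can pass a test with 3 samples against 3, and which direction prevailed depended on the setting. Peaks of a fold of at least 4 gave 121 gained and 4 lost regions, reciprocal overlap of 50% gave 152 and 87, summits clustered within 150 bp gave 122 and 88, and lists cut to equal length gave 40 and 70. Leaving out control A gave 28 gained and 632 lost regions, and leaving out H1 RNAi B gave 26 and 223. Leaving out control B, H1 RNAi A or H1 RNAi C gave 69, 92 or 52 gained regions. A rule on fewer samples is looser, so these counts could hardly fall.

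**Figure D3:**
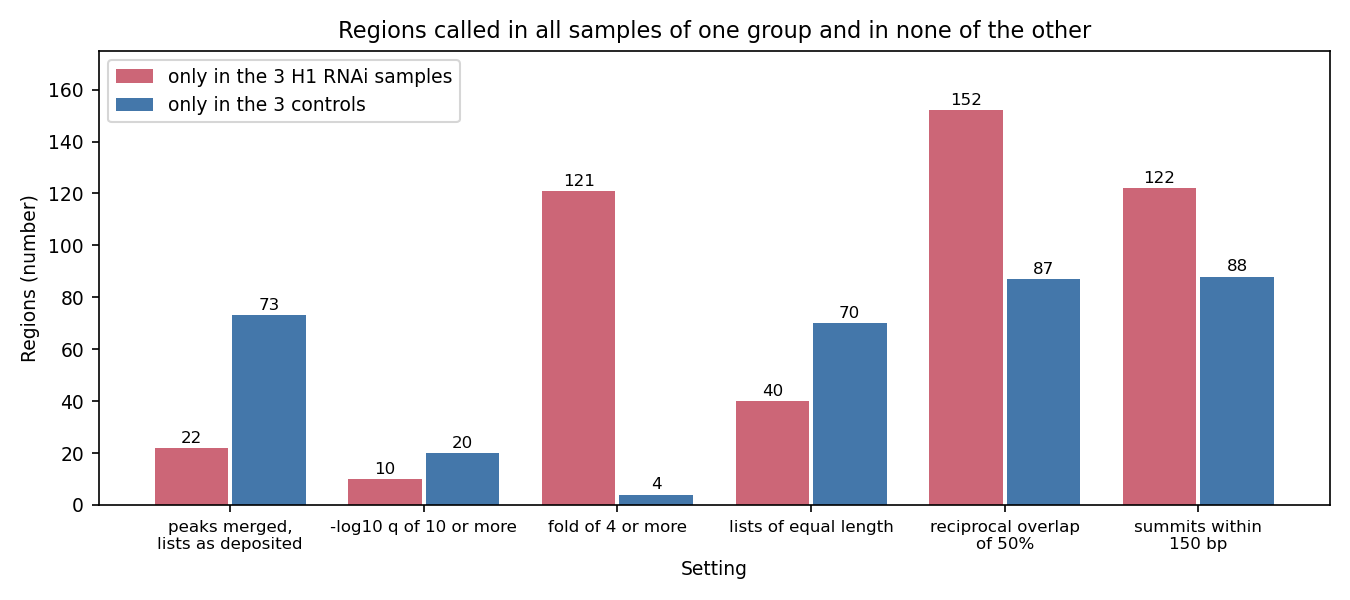
Number of regions (y axis) called in all 3 H1 RNAi samples and no control, or in all 3 controls and no H1 RNAi sample, under 6 settings (x axis). With reciprocal overlap and clustered summits, a region without a control call can still lie inside a control peak. Lost regions outnumber gained ones with merged peaks (73 against 22), and the order turns with a fold of at least 4 (121 gained, 4 lost), reciprocal overlap (152 and 87) and clustered summits (122 and 88).

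Among gained regions the highest-ranked lay 2 kb or less from cwo, which encodes a transcriptional repressor of the circadian clock (chromosome 3R, 10387017 to 10387187, between genes). Its weakest peak stood at the 85.6th percentile of its own list by the authors' q-value. The next in gene loci were a region within MSAmiP (3R, 16847286 to 16847498), one at gene ends of Gbs-76A and fal (3L, 19292478 to 19292987), where Gbs-76A encodes a glycogen-binding subunit of protein phosphatase 1, and one next to rn, a zinc-finger transcription factor gene (3R, 7310659 to 7310838). These 4 regions were also called in 3 of 3 H1 RNAi samples and no control with a −log10 q of at least 10, with a fold of at least 4 and with lists of equal length. MSAmiP held a second gained region (3R, 16882435 to 16882846).

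Further gained regions lay in Acsl, a long-chain acyl-CoA synthetase gene (2R, 8668837 to 8669003), at gene ends of drd and the ribosomal protein gene RpL37-1 (X, 15137132 to 15137625), and next to Sox21a, a Sox factor of the progenitors and the 1 gained region in the progenitor list (3L, 14109865 to 14110115, between genes). The other 8 of the 12 named gained regions, that at Sox21a among them, did not meet the rule with a −log10 q of at least 10 or with a fold of at least 4. Those at Dhc98D and dnc also failed with lists of equal length. The remaining named regions lay next to mtgo (2L, 16544002 to 16544176), at gene ends of Hyccin (2R, 17734527 to 17734852) and of the dynein heavy chain gene Dhc98D (3R, 28484515 to 28486216), in the body of the initiator caspase gene Dronc (3L, 9969643 to 9969931) and in dnc, a cAMP phosphodiesterase gene (X, 3273921 to 3274228). From Acsl to dnc, the weakest peak of each of these regions stood between the 37.4th and the 11.5th percentile of its list.

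Among lost regions, the highest named one lay within plum (3R, 26505303 to 26506141), at the 45.8th percentile in the list where it ranked lowest, followed by Lasp, an actin-binding protein gene (3L, 16693724 to 16694287), and a region at gene ends of cdi, mRpL55 and ATPsynD (3R, 19093608 to 19094999). GATAe, the GATA factor of the midgut and a member of the enterocyte list, had a lost region in its body (3R, 16014465 to 16015113), although its gene end had a peak in all 6 samples. Regulatory genes with lost regions included shn, a zinc-finger factor of Dpp signalling (2R, 11204483 to 11204939), S6k, the ribosomal protein S6 kinase (3L, 5807409 to 5808112), and Mi-2 with its neighbour Su(Tpl) (3L, 19900191 to 19900712), where Mi-2 encodes a nucleosome-remodelling ATPase. The others lay at IP3K1 (2L, 9785827 to 9786233), su(r) (X, 9200981 to 9202156), the filamin gene cher (3R, 17113767 to 17114060), SkpB and Smyd4-4 (2R, 12140302 to 12140845), and Ptpmeg, mthl10 and mth (3L, 341271 to 341726). Of 14 lost regions named here or found in a gene list, 7 met the rule with lists of equal length, 1 (plum) with a −log10 q of at least 10, and 0 with a fold of at least 4.

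No gene list was enriched at the threshold among gained or lost regions. As only 16 gained and 60 lost regions lay in gene loci, only a strong enrichment could have passed. Over 42 tests, 21 lists in each direction against 10597 regions in gene loci, each Benjamini-Hochberg adjusted two-sided Fisher exact p was 1. The replication-dependent histone list held 0 of these regions, so its tests could give no other value. The progenitor list had 1 of 16 gained regions (Sox21a) against 58 of all regions (unadjusted exact p = 0.0841). The ribosomal protein list had 1 gained region (RpL37-1) and 2 lost ones, at RpL27 (3R, 25684829 to 25685144) and RpS15Aa (X, 13337419 to 13338344), among 145 regions. The other list with a lost region was that of enterocyte genes (GATAe, 1 of 44 regions).

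Gained and lost regions differed in position from the regions shared by all 6 samples. By the summit of the strongest peak, 8 of 20 gained regions on placed chromosomes (40%; exact 95% interval 19.1 to 63.9%) lay between genes, against 475 of 4281 shared regions (11.1%; adjusted two-sided Fisher exact p = 0.00793). Lost regions lay at gene ends less often, 18 of 70 (25.7%) against 1796 of 4281 (42.0%; adjusted Fisher exact p = 0.0307). In a direct comparison of gained with lost regions, the share between genes was 40% against 17.1% (12 of 70, adjusted Fisher exact p = 0.190). This comparison passed without control A, B or C (adjusted Fisher exact p = 0.00866, 0.0209 and 0.0292) and without H1 RNAi B (0.0107). It did not pass in the remaining settings, and it turned without H1 RNAi C (20.8% against 25%). The calls against shared regions changed as follows. By the same Fisher exact tests, the call for gained regions ended with clustered summits (12.6% between genes, adjusted p = 0.997), with reciprocal overlap (14.8%, adjusted p = 0.434) and without H1 RNAi C (20.8%, adjusted p = 0.101). By the same exact tests, that for lost regions ended with lists of equal length (35.8%, adjusted p = 0.796), with clustered summits (37.9%, adjusted p = 0.997), and without H1 RNAi A (32.6%, adjusted p = 0.273) or H1 RNAi B (42.0%, adjusted p = 1).

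**Figure D4:**
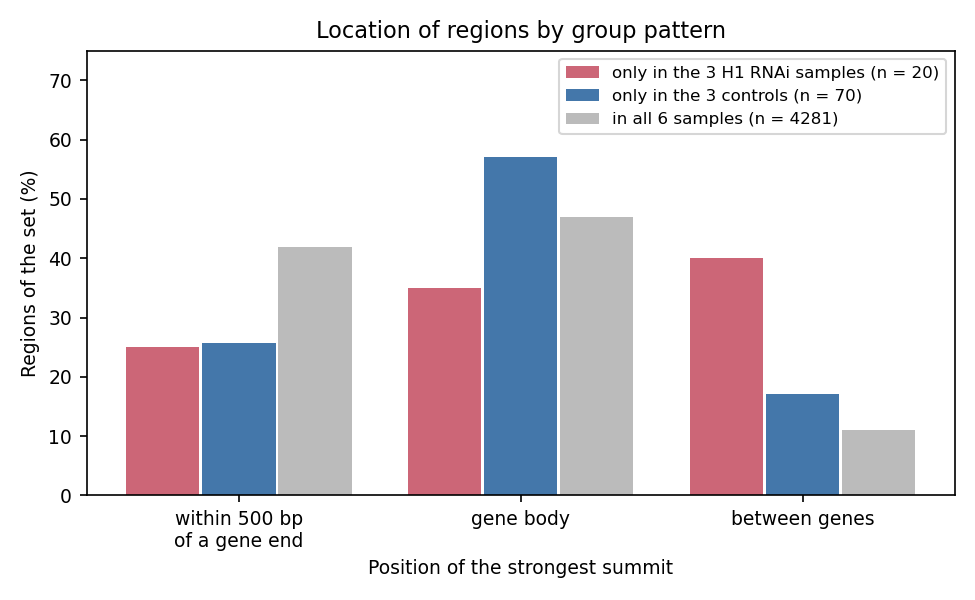
Share of regions (y axis, percent) whose strongest summit lies within 500 bp of a gene end, in a gene body or between genes, for regions called in the 3 H1 RNAi samples alone (n = 20), in the 3 controls alone (n = 70) and in all 6 samples (n = 4281). The share between genes is 40% for gained, 17.1% for lost and 11.1% for shared regions.

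On the TE sequence, 1 region was gained (279271 to 280008) and 3 were lost (25520 to 26156, 33077 to 33878 and 276320 to 277443). The gained one ranked second of the 22 gained regions, at a lowest percentile of 83.1. These regions fall outside the rule for named genes and were chosen after their values were seen. Of the 181 TE regions, 71 (39.2%) were called in all 6 samples, against 36.8% of the other regions.

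How much more the peak sets of one group resembled each other than those of different groups depended on single libraries. The mean pairwise Jaccard index over bases was 0.499 within controls, 0.582 within H1 RNAi samples and 0.505 between groups. The pairs within groups exceeded those between groups by 0.0350, and 3 of the 10 splits of the 6 samples into 3 and 3 gave a difference as large (exact permutation p = 0.3). The difference was 0.128 without control A and 0.00316 without H1 RNAi C. The pair with the lowest index was control A with control B (0.379), and the highest was control B with control C (0.679).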

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

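Alternatives for the position and list tests other than the exactly-3 background, the equal lengths and (for the lists) 2 of 3, and the runs without the TE sequence, were chosen after seeing the data. The counts of regions depended most on the setting. Asking for 2 of 3 or leaving out a sample loosens the rule, so those counts could hardly fall. Against 22 gained and 73 lost regions, a −log10 q of at least 10 gave 10 and 20, a fold of at least 4 gave 121 and 4, equal lengths 40 gained, reciprocal overlap 152 gained, clustered summits 122 gained, and 2 of 3 in place of 3 of 3 gave 125 and 669; leaving out single samples gave 26 to 92 gained and 82 to 632 lost. The arms alone (20 and 70) and lists without the TE sequence (21 and 70) stayed within 1.5 times. The difference in peak number turned to +882 with a fold of at least 4 and ranged from −1853 to 512 when single samples were left out. The share of peaks at gene ends turned to +0.355 points with 1000 bp and ranged from −2.59 to 1.29 points without single samples. With the fold minimum Delta had a gene-end peak in 1 more H1 RNAi sample than controls, while the stricter q, equal lengths and the wider window kept its direction. The difference in the share of peaks at gene ends was −4.86 with the stricter q, −5.23 with the fold minimum and −3.18 at equal lengths, against −0.976. Covered length, median width, the share on chromosome 4, Y and unplaced sequence and the Jaccard difference kept their direction but not their size. Without single samples, covered length ranged from −3.005 to −0.919 Mb (main −1.78; −0.464 with the fold minimum), and median width from −187 to −82.8 bp (main −126.5; −239 with the fold minimum). The chromosome share ranged from 0.0383 to 0.486 points (main 0.335) and the Jaccard difference from 0.00316 to 0.128 (main 0.0350). None of these exact tests can pass 0.05.

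Of the 9 position tests, 2 passed the threshold; 4 did with the exactly-3 background, 1 with equal lengths, 0 with clustered summits, 4 with reciprocal overlap, and 2 to 6 without single samples. Gained regions between genes fell to 14.8% with reciprocal overlap and 12.6% with clustered summits, with 20.8 to 43.5% without single samples. Lost regions at gene ends stood at 35.8% with equal lengths and 37.9% with clustered summits, with 24.1 to 42.0% without single samples. The causes were not tested beyond what follows for merging, which cannot decide. No list passed in any enrichment setting. The number of lists with groups apart went from 0 to between 0 and 3 without single samples. Male germline, hemocyte and ribosomal protein genes were lower in H1 RNAi without control A, and Polycomb targets higher without H1 RNAi A. Chance sets groups apart more often with 2 samples in a group than the 10% for 3 against 3. Control A also had the lowest share over all protein-coding genes, 29.0%, against 53.4% and 45.8% in controls B and C. With the replicate letter as a block, 2 lists moved one way in all 3 pairs (male germline lower, Polycomb targets higher), each at the smallest sign-flip p of 0.25. The counts of 22 gained and 73 lost regions cannot change under the replicate block, because such a region differs one way in any pairing. Lists of equal length turned the difference for JAK/STAT genes from 3.33 to −3.33 points and for heat shock genes from −3.70 to 3.70. They widened that for male germline genes from −5.80 to −10.1 and that for tracheal genes from 0 to −6.67. Differences for hemocyte (−8.33), enteroendocrine (−5.13) and enterocyte genes (−2.22), among others, went to 0. That for cell cycle genes shrank from −14.9 to −5.75. Whether the letters pair the samples stays open. Correlations of deviations were 0.0348, 0.0955 and −0.0504 for same-letter samples, and control A and control C correlated best with another letter. Peak number, however, rose in the order A, C, B in both groups. The motif search, the soft-masked share, and a block for the Jaccard difference were not run. Depth may limit the lists, since a site missing in control A or an H1 RNAi sample can lie below its threshold. Background cannot rank depth, as it also rises with fragment length.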

Other observations

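The sample splits, the counts with clustered summits and at equal lengths, and the background of regions called in exactly 3 samples were planned, while their use against the explanations below and all other tests in this part were chosen after the results were seen. In all 6 samples together, 3115 of 13946 protein-coding genes (22.3%) had a peak at a gene end, and 6024 had one in no sample. Intestinal progenitor genes were open far more often: 9 of 13 (69.2%) had a gene-end peak in each of the 6 samples, among them esg, N, klu, zfh2, Sox21a, Sox100B and mira (adjusted Fisher exact p = 0.00281). Among lists under the threshold, Polycomb-target developmental regulators followed with 32 of 72 (44.4%; adjusted Fisher exact p = 0.000287), including the Hox genes lab and Dfd, the segment polarity genes en and wg, and the limb gene Dll, while 24 of the 72, among them the Hox genes Antp, Ubx and Abd-B, had no gene-end peak in any sample. JAK/STAT genes stood at 50% (5 of 10; adjusted Fisher exact p = 0.178). The progenitor and Polycomb lists stayed under 0.05 with lists of equal length (adjusted Fisher exact p = 0.000581 and 1.61e-05) and without any single sample. Ribosomal protein genes stood at 35.6% (31 of 87; adjusted Fisher exact p = 0.0226), which ended with lists of equal length (25.3%; adjusted p = 0.334). In the E(spl) complex the gene ends of E(spl)m3-HLH, E(spl)mbeta-HLH, E(spl)malpha-BFM and E(spl)m6-BFM had peaks in 6 of 6 samples and 6 of the 11 genes in none. Of 26 enteroendocrine genes, sc, Ptx1 and mirr were open in all 6 samples, and 16, among them the hormone genes Tk, AstA, AstC and Dh31, had no gene-end peak in any.

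Of the 100 strongest regions common to the 6 lists, by the lowest of their 6 percentile ranks, 10 lay on the TE sequence, 5 on Y or unplaced scaffolds, 2 on the mitochondrial genome and 10 between genes. Within loci of genes with a symbol, the highest lay at drm (2L, 3545090 to 3545823), the G-protein-coupled receptor gene moody (X, 2049058 to 2050905), the zinc-finger gene btd (X, 9693773 to 9694227), disco (X, 16216677 to 16217769) and the cryptochrome gene cry (3R, 19211385 to 19212527). Each stood above the 99.0th percentile in each list (lowest 99.1). Counted by regions called in all 6 samples, the richest locus was Eip75B, an ecdysone-induced nuclear receptor gene, with 19 regions over 113.7 kb. Next came kirre with 15 over 394.1 kb, the Ets factor gene Eip74EF with 13 over 60.7 kb, and the ecdysone receptor gene EcR, Tlk and bun with 12 each. Long genes hold more regions by their length alone, and no theme was tested here.

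The excess of lost over gained regions (73 against 22) depended on how regions were built. The median H1 RNAi peak was narrower, though not beyond the spread between samples. A narrow peak that touches a wide control peak is merged with it and not counted as gained. The control peak is then not counted as lost either. With summits clustered within 150 bp there were 122 gained and 88 lost regions. Clustering can add gained sites inside wide control peaks, so these counts cannot tell whether merging caused the excess. Unequal lists stay open as a further cause: at equal lengths lost regions exceeded gained ones by 30, while another split differed by up to 59. Of the 10 splits of the samples, 3 gave as many regions as the real one (95 regions, highest other 570, which set the 3 shortest lists, control A, H1 RNAi A and H1 RNAi C, apart from the 3 longest and so points to list length). At equal lengths 1 of the 10 splits, the real one, gave as many (110, highest other 97); 10 splits are too few for a share under 0.05. An effect of H1 on single sites is open.

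Gained regions between genes are the pattern a biologist might follow up, at cwo, rn, Sox21a, mtgo and 4 sites outside gene loci, 2 of them in centromere-proximal 3L (25206437 to 25206808 and 25209868 to 25210177). Whether partly called regions in general lie between genes was asked with the other regions called in exactly 3 samples. Of these, 12.9% did, below the interval of the gained share (19.1 to 63.9%). However, 570 of the 1128 regions called in exactly 3 samples were those of control B, control C and H1 RNAi B. The share therefore speaks largely for that pattern and cannot decide the question for partly called regions in general. Centromere-proximal spans were bounded by listed heterochromatic genes, with no measure of repeats. They held 2 of 20 gained regions against 18 of 4247 shared ones (Fisher exact p = 0.00377). Outside these spans 33.3% of gained regions (6 of 18, exact 95% interval 13.3 to 59.0%) still lay between genes, against 11% of shared ones. The spans lay on 2L, 2R, 3L and 3R alone, and a gained site between genes on X (22386748 to 22387141) counted as outside. A centromere-proximal origin therefore cannot be excluded. Clustered summits gave 12.6% between genes, but they add gained sites inside wide control peaks. Such added sites can dilute the share, so whether the way peaks are joined is a cause stays undecided. Gained regions also had neighbours within 50 kb more often than random sets of regions called in 3 samples or fewer (2 pairs against a mean of 0.186; permutation p = 0.0144; 1 pair is the 3L sites, and the other lies in the body of MSAmiP and so not between genes), which a haplotype or transgene of the RNAi strain could give as well as local opening; the 2 cannot be told apart because genotype and treatment coincide.

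Narrower peaks and the shorter covered length of the H1 RNAi lists may reflect fragment length. Median width followed the shortest peak of each list, which the caller usually ties to its fragment length, over the 6 samples (Pearson r = 0.938, exact permutation p = 0.00278, adjusted 0.00556; Spearman rho = 0.943, exact permutation p = 0.0167; r = 0.848 without control C and H1 RNAi B). Both widths come from the same list, so a positive relation is partly built in. Fragment length itself was not measured, and the relation cannot show that it is the cause. The ratio of median to shortest width was 3.12 ± 0.214 in controls and 2.89 ± 0.268 in H1 RNAi samples (SD, n = 3 each; exact permutation p = 0.3). Covered length followed background (Pearson r = 0.857, exact permutation p = 0.0222, adjusted 0.0222; Spearman rho = 0.6, exact permutation p = 0.242), but r was −0.344 without controls B and C, so the relation rests on those samples and depth stays open. Background also rises with the length to which fragments are extended, so this relation does not separate depth from fragment length. Whether H1 depletion itself changes fragment length was not tested.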
